A study of Rattus norvegicus with 16 samples.

How the data were processed

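RNA of cultured primary pancreatic islets from male Wistar rats was measured on 1-colour Affymetrix expression arrays. The islets were left untreated (n = 5 arrays), received an adenovirus carrying bacterial β-galactosidase (Adβgal, the control virus, n = 6) or received an adenovirus carrying the transcription factor Nkx6.1 (AdNkx6.1, n = 5). Per the labels' protocols the rats were 8 weeks old, the medium held 8 mM glucose and 10% serum, virus was present for 18 h, and islets were collected at 48 h. The titles call the arrays biological replicates. The treatment protocol states 5 replicates for each condition, whereas the table holds 6 Adβgal arrays, and all 6 were used.

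The deposited table holds probe set intensity values on a linear scale, from 6.25 to 35765, with no missing values. The submitters' processing notes name the tool RMA, which corrects background, normalizes between arrays and summarizes probes into probe sets; its version and the later return to a linear scale are not described in the sources used here. The design assumed log2 values, so log2 of each deposited intensity was taken and no pseudocount was added. The median intensity per array lay between 264.8 and 296.2. Detection calls were not used here, so dim probe sets were kept and a fold against a low intensity is not exact. The number of arrays limits the precision of every value.

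Of 31099 probe sets, 57 were controls and left out of all gene tests. Of the other 31042, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had none. The gene number of 20758 probe sets matched the symbol table, which changed 0 symbols. Each gene was represented by its probe set of highest mean over the 16 arrays, which gave 14217 genes. Another 10216 probe sets, those with several symbols or none, entered no gene comparison. Of the tested genes, 4525 had more than 1 probe set.

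Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) in 1 fit over the 3 groups, which share an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the 14217 genes of a comparison, all tests were 2-sided, and the threshold was an adjusted p of 0.05. Each log2 change is the first group minus the second and is given with its standard error (SE) from that fit; folds are printed above 1 with their direction in words. A further count required a change of at least 1.5-fold. Tables were prepared with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.

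The script was tested on simulated data for the 14217 genes, with 50 genes changed at each fold size. At 1.5-fold, 70% were recovered for AdNkx6.1 against Adβgal, 78% for Adβgal against untreated and 58% for AdNkx6.1 against untreated. At 2-fold these shares were 92%, 90% and 84% in the same order. False calls numbered 11, 12 and 7, and simulated data without changes gave 0 calls in each comparison. The simulation drew each gene independently and with the same spread in all groups. In the real data the SD of the difference between 2 arrays of a group reached 0.709 with Adβgal and 0.267 untreated. These rates may therefore not hold for the real arrays.

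The gene lists, 21 in number, were fixed with the comparisons, the naming rule and the other settings tried before the data were examined: beta cell identity and glucose sensing, other islet endocrine cells, secretory granule and exocytosis, DNA replication and S phase, G2 and mitosis, cell cycle inhibitors, the anaphase promoting complex, NR4A receptors and immediate early genes, interferon response, NF-κB and inflammation, p53 targets, endoplasmic reticulum stress, glycolysis and glucose transport, oxidative phosphorylation, cholesterol synthesis, beta cell disallowed genes, and markers of acinar cells, duct cells, endothelial cells, stellate cells with fibroblasts, and macrophages with leukocytes. Some genes stand in more than 1 list. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over 63 tests (21 lists in 3 comparisons). Camera with a correlation estimated from the data and limma's fry were run beside it. A count "adjusted over the list alone" adjusts the p-values of the members of 1 list among themselves.

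Genes named in the text follow a fixed rule. In every comparison it takes Nkx6-1, Nr4a1 and Nr4a3, which the series title names. It adds the 10 highest and 10 lowest changes past the threshold in AdNkx6.1 against Adβgal and in Adβgal against untreated, and the 5 highest and 5 lowest in AdNkx6.1 against untreated, skipping placeholder symbols. Up to 4 members of each list with the smallest p could be named or left out. Genes outside the rule are said to be chosen after their values were seen.

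The overlap of the comparisons that share the untreated arrays was set beside 100 simulated draws of unchanged groups, beside the overlap of independent lists, and beside 10 splits of the untreated arrays. The other settings were the replicate number as a fixed or random block, a fit of only the 2 groups compared, a variance trend with robust moderation, array weights, centring on array medians, quantile normalization again, leaving out the dimmest 40% of probe sets, the mean of a gene's probe sets, every probe set on its own, and leaving out each replicate. Leaving out Adβgal replicates 4, 5 and 6 together, and a covariate for the actin 3'/5' ratio, a measure of RNA integrity from the control probe sets, were chosen after seeing the data. The counts of changed genes were set beside those of 100 splits of the arrays into groups of the same sizes. Arrays far from the rest of their group were found with Dixon's gap test. Probe sets without a gene name were set beside named ones in 4 bins of mean intensity; an earlier range, taken from the probe sets called higher, was dropped because it depends on the calls. A list of 35 measured spermatid genes was written after the data were seen. Columns of other series numbered 0.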

Results

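Gene expression was measured on 16 arrays of rat islets 48 h after the start of treatment: 5 untreated, 6 with the control virus Adβgal and 5 with AdNkx6.1. Islets are the endocrine clusters of the pancreas, and most of their cells are insulin-producing beta cells. Nkx6.1 is a transcription factor of beta cells. The series title ties it to beta cell proliferation and to the nuclear receptors Nr4a1 and Nr4a3. Values are log2 intensities of 1 probe set per gene, given as mean ± SD or as a log2 change ± SE. Median intensities of the arrays ran from 264.8 to 296.2.

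AdNkx6.1 against Adβgal asks what the virus with the delivered factor changes beyond the control virus. The doses of the viruses were not compared, so no difference between these groups can be tied to the factor alone. Both NR4A receptors of the title and the immediate early genes Fosb and Fos were higher with AdNkx6.1. So were 33 of 44 listed genes of DNA replication and 31 of 50 of mitosis, while 8 of 17 listed genes of other islet endocrine cells were lower; these lists passed camera at its preset correlation but not with an estimated one (0.1, 0.18 and 0.18). Nr4a1 rose 2.97-fold, from 6.93 ± 0.48 (n = 6) with Adβgal to 8.5 ± 0.06 (n = 5), a log2 change of 1.57 ± 0.17 with a limma adjusted p = 6.9e-06. Nr4a3 rose 5.53-fold, from 6.65 ± 1.15 to 9.12 ± 0.34, a log2 change of 2.47 ± 0.41 with adjusted p = 0.00034. In both genes every AdNkx6.1 array lay above every Adβgal array. Of the other probe sets of Nr4a3, the brighter was higher by 1.61 ± 0.24 and the dimmer differed by -0.16 ± 0.1; with the mean of all probe sets of a gene the change of Nr4a3 was 1.31. Nkx6-1 itself was 1.38-fold lower with AdNkx6.1, at 11.43 ± 0.17 against 11.9 ± 0.19, a log2 change of -0.46 ± 0.1 with adjusted p = 0.0023. The sources used here do not say whether this probe set lies within the delivered sequence, so it does not check the group labels.

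**Figure D1:**
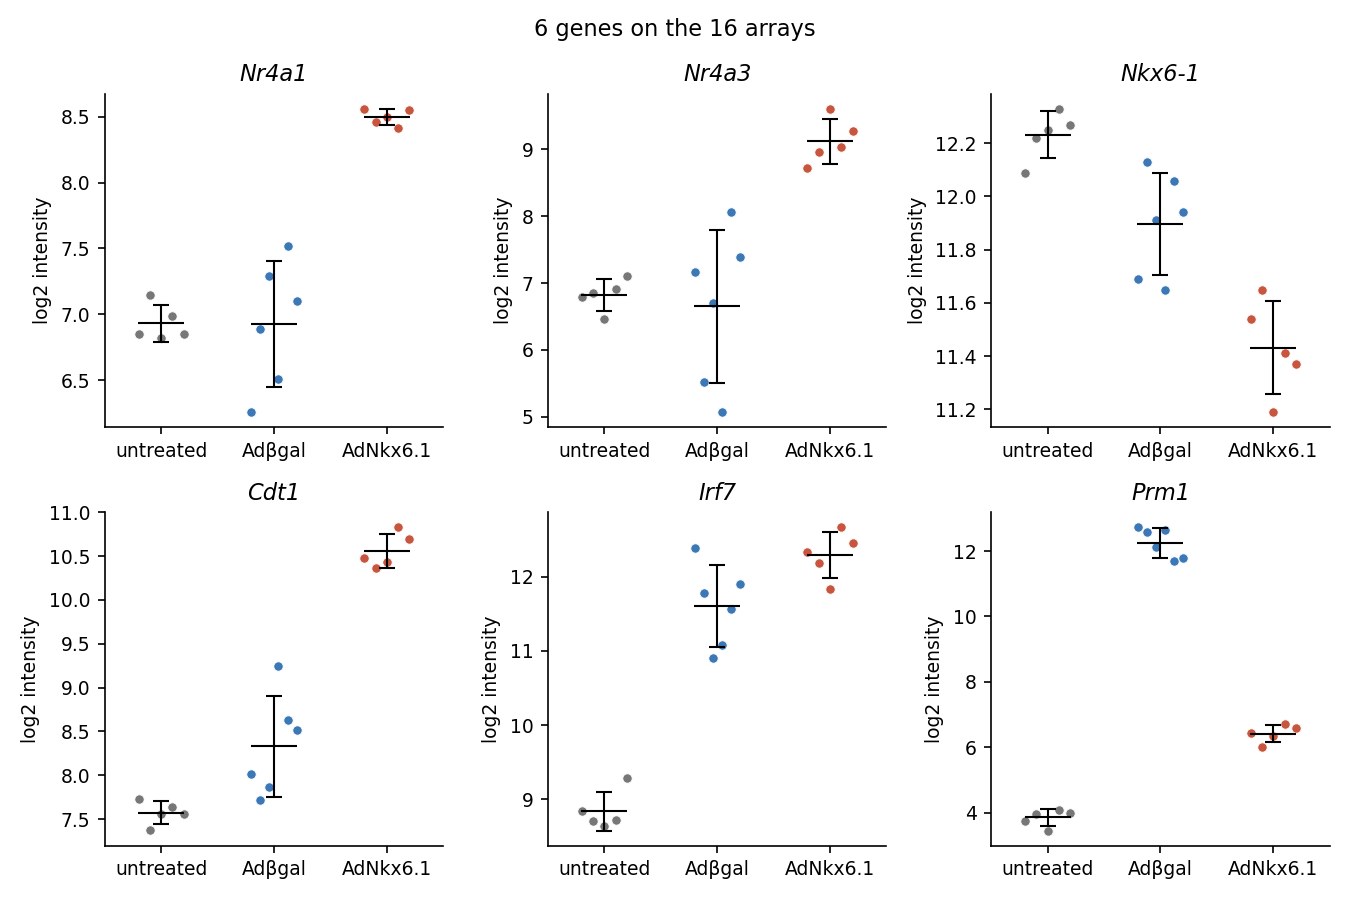
Log2 intensity of 6 genes on each of the 16 arrays by group (points), with the group mean (line) and SD (bars). Nr4a1 and Nr4a3 lie higher on the AdNkx6.1 arrays than on all others, Nkx6-1 has group means of 12.23 untreated, 11.9 with Adβgal and 11.43 with AdNkx6.1, and Prm1 has group means of 3.85 untreated, 12.26 with Adβgal and 6.41 with AdNkx6.1.

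In all, 3560 of 14217 genes changed between AdNkx6.1 and Adβgal, 2354 higher and 1206 lower, and 1437 of them changed at least 1.5-fold (1058 higher, 379 lower). Slc5a5, the sodium iodide symporter, had the highest fitted rise, at 41.1-fold (9.55 ± 0.2 against 4.19 ± 0.43). It was followed by Bpifb1, a secreted BPI-fold protein, at 31.5-fold, Ly6i, a surface protein of the Ly6 family, at 28.8-fold, Catsperz, a subunit of a sperm cation channel, at 22.7-fold, and Galnt6, an enzyme of mucin-type glycosylation, at 21.5-fold. The steroid dehydrogenase Hsd17b2 rose 15.9-fold, the acute phase gene Saa3 15-fold, the fibrinogen gene Fga 12.6-fold, the hair follicle gene Tchh 12.4-fold and Bpifa5 12-fold. With Adβgal, Slc5a5, Ly6i (4.13), Hsd17b2 (3.97), Fga (4.45), Tchh (4.33) and Galnt6 (4.98) lay low on the intensity scale and no detection call was used, so their folds and the order of the 10 genes are not exact. Adjusted p-values of these 10 genes lay between 8.4e-13 and 1.8e-06, and each separated all AdNkx6.1 from all Adβgal arrays. With the mean of all probe sets of a gene the log2 change of Fga was 2.64, against 3.65.

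The largest fall was in Prm1, a protamine of sperm, at 57.4-fold (6.41 ± 0.27 against 12.26 ± 0.45, adjusted p = 1.7e-11). Prm1 was 339-fold higher with Adβgal than untreated, where 0 of 35 other spermatid genes were higher past the threshold. Serpini2, a pancreatic serpin, fell 4.67-fold, and Ptf1a, the transcription factor of acinar cells, fell 4.33-fold. The noncoding genes Lnc215 and Mir384 fell 4.2-fold and 3.62-fold, the glucuronosyltransferases Ugt2b15 and Ugt2b35 fell 4.1-fold and 3.62-fold, and the retinaldehyde dehydrogenase Aldh1a1 fell 3.84-fold. Cpa1, an acinar carboxypeptidase, fell 3.55-fold (adjusted p = 0.014), but without Adβgal replicates 4, 5 and 6 its log2 change was -0.93, against -1.83, with an adjusted p of 0.19. Smooth muscle actin Actg2 fell 4.11-fold at an adjusted p = 0.049, which became 0.065 to 0.11 when any 1 of the AdNkx6.1 arrays or Adβgal replicate 4, 5 or 6 was left out. Leaving out these 3 Adβgal arrays together, which carried high acinar and leukocyte markers, gave Actg2 a log2 change of -0.31 (adjusted p = 0.54), against -2.04. In the same setting the changes were smaller but still called for Serpini2 (-1.53, against -2.22), Ptf1a (-1.48, against -2.11), Lnc215 (-1.12, against -2.07) and Mir384 (-1.19, against -1.85).

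Of the DNA replication and S phase list, 33 of 44 measured members rose and 0 fell; adjusted over the list alone, 37 rose. Cdt1, which licenses replication origins, rose 4.68-fold, thymidine kinase Tk1 3.59-fold, cyclin E gene Ccne1 3.15-fold and the replicative helicase gene Mcm5 2.92-fold. Camera gave the list an adjusted p = 6.1e-16, and adjusted p = 0.1 with an estimated correlation. Of the G2 and mitosis list, 31 of 50 rose and 0 fell, with 32 higher when adjusted over the list alone. Aurora kinase gene Aurka rose 2.94-fold, cyclin F gene Ccnf 2.48-fold, Mybl2, a transcription factor of cycling cells, 2.03-fold and the spindle kinesin gene Kif11 1.87-fold. The list had adjusted p = 1.3e-10, and adjusted p = 0.18 with an estimated correlation. Without Adβgal replicates 4, 5 and 6 the counts were 39 of 44 and 34 of 50 higher.

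Cell cycle inhibitors rose beside them in 8 of 23 cases, with 0 lower and also 8 higher adjusted over the list alone. Cdkn1c rose 11.8-fold, Gadd45b 3.4-fold and Cdkn1a 2.08-fold. The list did not pass (camera adjusted p = 0.082, and adjusted p = 0.36 with an estimated correlation). Members of the anaphase promoting complex list, which drives exit from mitosis, rose in 5 of 20 cases, likewise 5 adjusted over the list alone, among them Fzr1 1.59-fold and Ube2s 1.43-fold; camera gave adjusted p = 0.14, and adjusted p = 0.5 with an estimated correlation. Of the p53 targets, 9 of 23 rose, including Xpc 1.64-fold and Bbc3 1.59-fold, and 1 fell; adjusted over the list alone 11 rose and 2 fell. That list had adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation, and its p was 0.08 without Adβgal replicates 4, 5 and 6.

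**Figure D2:**
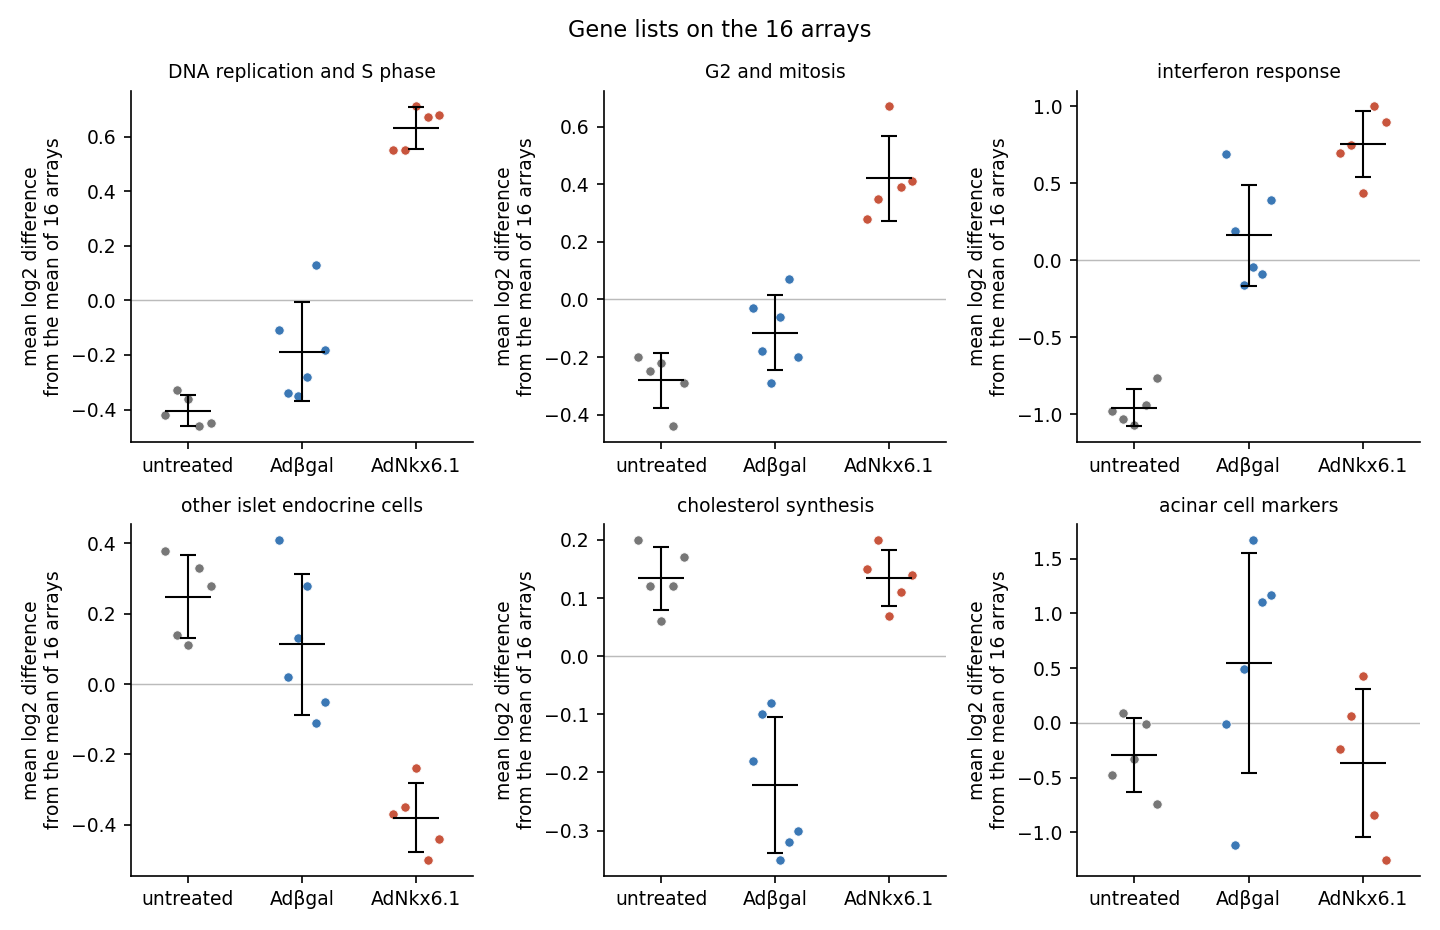
Mean log2 difference of 6 gene lists on each array from their mean over the 16 arrays, by group (points), with group mean (line) and SD (bars). The replication and mitosis lists are highest with AdNkx6.1, the interferon list is lowest on untreated arrays, and the acinar list spans -1.12 to 1.67 among the Adβgal arrays.

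Of the NR4A and immediate early gene list, 13 of 38 rose and 5 fell; adjusted over the list alone 15 rose and 5 fell. The series title draws Nr4a1 and Nr4a3 from this study, so for these members the list is not independent evidence. Fosb rose 6.74-fold, Maff 2.69-fold and Fos 2.38-fold, all immediate early transcription factors. With the mean of all probe sets of a gene the log2 change of Fos was 0.64, against 1.25, and without Adβgal replicates 4, 5 and 6 that of Fosb was 3.45, against 2.75. Camera gave it adjusted p = 0.02, adjusted p = 0.53 with an estimated correlation, and adjusted p = 0.053 without Adβgal replicate 2. Of the interferon response list, 23 of 45 rose and 0 fell, with 26 higher adjusted over the list alone. Oasl, an antiviral protein gene, rose 4.85-fold, the immunity GTPase gene Igtp 2.34-fold and the immunoproteasome genes Psmb8 and Psmb9 2.13-fold and 2.05-fold. The list had adjusted p = 3.2e-08, and adjusted p = 0.37 with an estimated correlation. Without Adβgal replicates 4, 5 and 6, 17 of 45 rose. Its mean per array overlapped between the groups, at -0.16 to 0.69 with Adβgal and 0.44 to 1 with AdNkx6.1. The doses of the 2 viruses were not compared here. For this list, as for the others in this comparison, a difference between the viruses therefore cannot be told from an effect of the factor.

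Of the list for other islet endocrine cells, 8 of 17 fell and 0 rose, with 10 lower adjusted over the list alone. Rbp4 fell 2.2-fold, Dpp4 2.17-fold, Hhex, a transcription factor of delta cells, 1.9-fold and the peptide hormone gene Pyy 1.45-fold. Its camera test gave adjusted p = 3.3e-05, and adjusted p = 0.18 with an estimated correlation. Of the beta cell identity list, 3 of 20 fell and 0 rose, and likewise 3 adjusted over the list alone: the transcription factor genes Pax6 (1.23-fold, adjusted p = 0.0037) and Pdx1 (1.24-fold, adjusted p = 0.027), and the potassium channel gene Kcnj11 (1.19-fold, adjusted p = 0.033). Of these 20, 9 fell without Adβgal replicates 4, 5 and 6 (median -0.26, adjusted p = 2e-05), and with quantile normalization again 6 fell. The call of Pdx1 was lost without Adβgal replicate 2 or 3 or AdNkx6.1 replicate 2, 3 or 5, at adjusted p-values of 0.052 to 0.073. The call of Kcnj11 was lost without Adβgal replicate 1, 2 or 3 or AdNkx6.1 replicate 3, 4 or 5, at 0.06 to 0.086, and with the mean of all its probe sets, where its log2 change was -0.07, against -0.25 (adjusted p = 0.76). The list had adjusted p = 0.0019, and adjusted p = 0.29 with an estimated correlation. Of the secretory granule list, Vgf, a neuropeptide precursor gene, rose 11.9-fold and the exocytosis gene Stx1a 1.98-fold, while Snap25 fell 1.17-fold and Syt4 1.2-fold, the last not called with the mean of all its probe sets (-0.25, adjusted p = 0.34). The other 25 of 29 did not pass, the same 4 passed adjusted over the list alone (2 higher, 2 lower), and the list did not pass (adjusted p = 0.96, and adjusted p = 0.98 with an estimated correlation; median -0.01, mean 0.19). Of the granule list 2 rose and 4 fell without Adβgal replicates 4, 5 and 6.

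Of the cholesterol synthesis list, 8 of 19 rose and 1 fell; adjusted over the list alone the counts were also 8 and 1. Mevalonate kinase gene Mvk rose 2.93-fold, Tm7sf2 2.21-fold, Dhcr7 1.76-fold and Mvd 1.72-fold. Camera gave this list adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation, and adjusted p = 0.08 without Adβgal replicates 4, 5 and 6, which had the lowest values of this list on any array (-0.35, -0.32 and -0.3). Of the glycolysis list, 9 of 22 rose and 2 fell, with 11 and 2 adjusted over the list alone. The aldolase gene Aldoc rose 2.9-fold, the isomerase gene Gpi 1.41-fold and enolase gene Eno1 1.28-fold, and Pdk4, which restrains pyruvate oxidation, fell 1.81-fold; the list had adjusted p = 0.013, and adjusted p = 0.34 with an estimated correlation. Of the oxidative phosphorylation list, 10 of 46 rose and 0 fell, with 8 higher adjusted over the list alone. Cyc1 rose 1.28-fold and Cox5a 1.19-fold. That list had adjusted p = 0.016, and adjusted p = 0.63 with an estimated correlation; the p was 0.058 without AdNkx6.1 replicate 4, 0.13 without Adβgal replicate 5 and 0.51 without Adβgal replicates 4, 5 and 6, where 5 members rose.

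The acinar marker list had a median change of -0.92 and camera adjusted p = 5.1e-05, and adjusted p = 0.53 with an estimated correlation. Of 26 members, 3 fell (Ptf1a, Cpa1 and Cuzd1) and 0 rose; 2 fell adjusted over the list alone. The acinar list mean was 1.67, 1.1 and 1.17 on Adβgal replicates 4, 5 and 6, and -0.01, -1.12 and 0.49 on replicates 1, 2 and 3. Without replicates 4, 5 and 6, a choice made after seeing the data, the median change was -0.08 with adjusted p = 0.26, 1 member was lower, and Cuzd1 had a log2 change of -0.58, against -1.22, with an adjusted p of 0.26. The call of Cuzd1 was also lost without AdNkx6.1 replicate 4 (adjusted p = 0.071) or 5 (0.089) or Adβgal replicate 6 (0.059). The leukocyte list had adjusted p = 0.0068 towards lower values, adjusted p = 0.59 with an estimated correlation, 0.07 without Adβgal replicate 6 and 0.88 without replicates 4, 5 and 6. Of its 29 members, the T cell kinase gene Lck rose 2.13-fold and the macrophage gene Adgre1 fell 1.57-fold, and the same counts held adjusted over the list alone, 1 higher and 1 lower; without replicates 4, 5 and 6 the log2 change of Adgre1 was -0.27, against -0.65 (adjusted p = 0.074).

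Of the duct marker list, 6 of 17 rose and 1 fell, with 7 and 3 adjusted over the list alone. Cd24 rose 1.66-fold and the keratin genes Krt8, Krt18 and Krt7 rose 1.49-fold, 1.44-fold and 1.27-fold. The list did not pass (adjusted p = 0.11, and adjusted p = 0.53 with an estimated correlation). Of the genes usually silent in beta cells, called disallowed, 6 of 24 rose, among them the sulfurtransferase gene Tst 4.76-fold, and 5 fell, among them Lmo4 1.4-fold; adjusted over the list alone the counts were the same 6 and 5. Its median was -0.05, its mean 0.08 and its adjusted p = 0.6, and adjusted p = 0.87 with an estimated correlation. Without Adβgal replicates 4, 5 and 6, 8 disallowed genes rose and 3 fell, with a median of 0.13 (camera adjusted p = 0.33). Of the NF-κB list, 4 of 37 rose and 2 fell, with 3 and 1 adjusted over the list alone; Icam1, an adhesion molecule gene, rose 3.15-fold and the cytokine gene Il15 fell 1.95-fold (median -0.1, mean 0, adjusted p = 0.47, and adjusted p = 0.82 with an estimated correlation); without Adβgal replicates 4, 5 and 6, 8 rose and 1 fell. Of the endoplasmic reticulum stress list, 2 of 39 rose and 3 fell, the same adjusted over the list alone, with Wfs1 1.88-fold higher and the cystine transporter gene Slc7a11 1.67-fold lower (adjusted p = 0.073, and adjusted p = 0.72 with an estimated correlation; 0.0044 without Adβgal replicates 4, 5 and 6, where 2 rose and 6 fell).

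Of 20 endothelial markers, Flt4 fell 1.2-fold (adjusted p = 0.047), and of 25 stellate and fibroblast markers, Dcn fell 1.28-fold (0.023) and Tagln 1.33-fold (0.045); adjusted over the list alone 0 passed in either list. The call of Flt4 was lost without AdNkx6.1 replicate 1, 3, 4 or 5 or Adβgal replicate 2, 3, 4, 5 or 6, at adjusted p-values of 0.053 to 0.12. The call of Tagln was lost without any 1 of the AdNkx6.1 arrays or Adβgal replicate 4, 5 or 6, at 0.057 to 0.1, and that of Dcn without AdNkx6.1 replicate 1, at 0.061. Without Adβgal replicates 4, 5 and 6 together the log2 changes were -0.29 for Flt4 (against -0.27; adjusted p = 0.084), -0.17 for Dcn (against -0.35; 0.24) and -0.1 for Tagln (against -0.41; 0.45). Both lists had adjusted p = 0.12, with an adjusted p = 0.75 and an adjusted p = 0.71, respectively, with an estimated correlation.

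Camera passed 12 of 21 lists for AdNkx6.1 against Adβgal. With an estimated correlation 0 passed, 3 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 13. Without Adβgal replicates 4, 5 and 6 camera passed 8 lists, and 4028 genes changed.

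**Figure D3:**
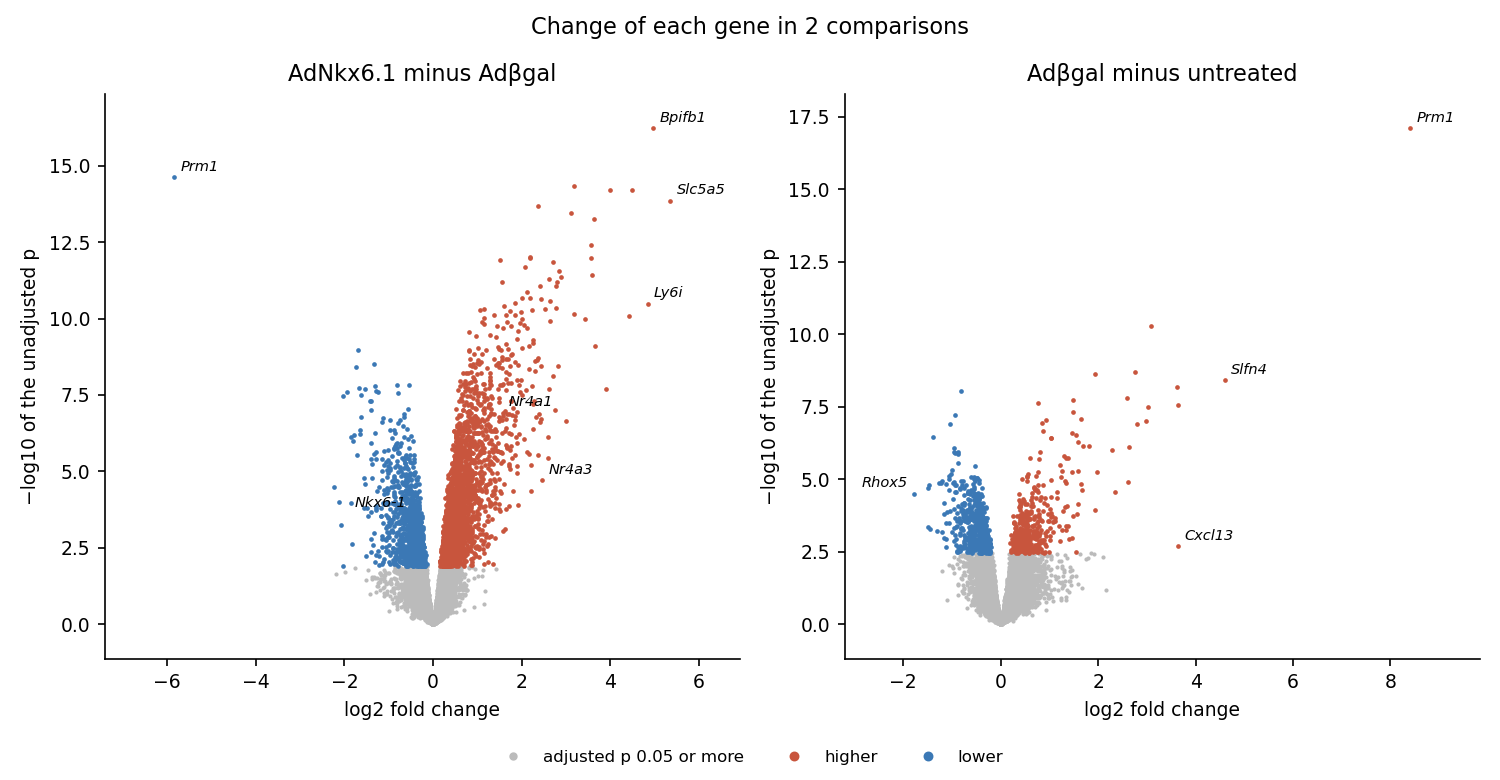
Log2 fold change of each gene (horizontal) against -log10 of its unadjusted limma p (vertical) for AdNkx6.1 minus Adβgal (left) and Adβgal minus untreated (right), with genes higher and lower past the threshold coloured. On the left 2354 genes are higher and 1206 lower, on the right 404 and 593, and Prm1 lies at -5.84 and 8.41.

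Adβgal against untreated asks what the control virus itself changes. With Adβgal 30 of 45 listed interferon response genes were higher, and 11 of 19 genes of cholesterol synthesis and 5 of 20 of beta cell identity were lower; these lists passed camera at its preset correlation but not with an estimated one (0.1, 0.1 and 0.18). Prm1 had the highest fitted rise, at 339-fold (12.26 ± 0.45, n = 6, against 3.85 ± 0.25, n = 5; adjusted p = 1.1e-13), where the low untreated intensity makes the fold inexact. It was followed by Slfn4, an interferon-induced gene, at 24.3-fold, the antiviral genes Ifit3 at 12.5-fold, Mx1 at 12.3-fold and Mx2 at 7.88-fold, and the helicase gene Ddx60 at 8.13-fold. The major histocompatibility gene RT1-T24-3 rose 8.52-fold, the ubiquitin-like modifier gene Isg15 6.91-fold and the transcription factor gene Irf7 6.8-fold. The chemokine gene Cxcl13 rose 12.5-fold with an SD of 2.3 among Adβgal arrays and an adjusted p = 0.036. That call was lost when any 1 untreated array or Adβgal replicate 4, 5 or 6 was left out, at 0.054 to 0.082, and without replicates 4, 5 and 6 together the log2 change was 1.69, against 3.65 (adjusted p = 0.25). Cxcl13 was highest, at 11.04, 10.78 and 10.91, on Adβgal replicates 5 and 6 and AdNkx6.1 replicate 1, the arrays with the highest means of the B cell genes Cr2, Ms4a1 and Iglc1 (7.36, 7.13 and 6.74; chosen after their values were seen). For Slfn4 the mean of all probe sets of a gene gave a log2 change of 2.27 and array weights gave 4.01, against 4.6.

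Among the lowest with Adβgal, the homeobox gene Rhox5 fell 3.43-fold, carbonic anhydrase gene Car3 2.81-fold, collagenase gene Mmp13 2.8-fold and the fatty acid desaturase gene Scd 2.79-fold. Sfrp4, a secreted Wnt antagonist gene, fell 2.62-fold, the potassium channel gene Kcnk2 2.39-fold and the proteoglycan gene Fmod 2.35-fold. The log2 change of Rhox5 was -1.12 without Adβgal replicates 4, 5 and 6, against -1.78, and with the mean of all probe sets of a gene those of Sfrp4 and Kcnk2 were -0.64 and -0.62, against -1.39 and -1.26. Fstl5 fell 2.75-fold and the ion channel gene Asic2 2.46-fold, but without Adβgal replicates 4, 5 and 6 their log2 changes were -1.11 and -0.76, against -1.46 and -1.3, with adjusted p-values of 0.061 and 0.092. The macrophage gene Trem2 fell 2.32-fold, and its adjusted p became 0.052, 0.054 and 0.051 without untreated replicate 1, 4 and 5. Without Adβgal replicates 4, 5 and 6 its fall was larger, at a log2 change of -1.79 (adjusted p = 9.7e-05). Nr4a1 and Nr4a3 did not differ past the threshold, with log2 changes of -0.01 ± 0.17 (adjusted p = 0.99) and -0.17 ± 0.41 (adjusted p = 0.83). Nkx6-1 had a log2 change of -0.33 ± 0.1 that missed the threshold at an adjusted p = 0.051, and passed it without Adβgal replicate 2 (0.023) or 5 (0.036). It also passed with a variance trend and robust moderation (0.035), array weights (0.02), centring on medians (0.024), without the dimmest 40% of probe sets (0.04) and with the actin covariate (0.019), while without Adβgal replicates 4, 5 and 6 together its adjusted p was 0.12.

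Of the interferon response list, 30 of 45 rose and 0 fell, with 35 higher adjusted over the list alone; the list had adjusted p = 4.4e-34, and adjusted p = 0.1 with an estimated correlation. Without Adβgal replicates 4, 5 and 6, 28 rose. Of the cholesterol synthesis list, 11 of 19 fell and 0 rose, with 14 lower adjusted over the list alone. Idi1 fell 1.68-fold, the sterol carrier gene Stard4 1.44-fold, Dhcr7 1.42-fold and squalene synthase gene Fdft1 1.39-fold. The list had adjusted p = 3.2e-08, and adjusted p = 0.1 with an estimated correlation; its lowest arrays were Adβgal replicates 4, 5 and 6, and without these 7 members fell. Of the beta cell identity list, 5 of 20 fell and 0 rose, including the transcription factor genes Nkx2-2 1.46-fold, Neurod1 1.43-fold and Foxa2 1.36-fold. Adjusted over the list alone 9 fell and 1 rose, and the list had adjusted p = 9.9e-05, and adjusted p = 0.18 with an estimated correlation. Of the secretory granule list, 6 of 29 fell and 0 rose, with 13 lower adjusted over the list alone. Ptprn2, a granule membrane protein gene, fell 1.45-fold, Syt5 1.43-fold and Rab3b 1.37-fold, the last at -0.46, against -0.25 (adjusted p = 0.08) without Adβgal replicates 4, 5 and 6. For it camera gave adjusted p = 8.4e-06, and adjusted p = 0.27 with an estimated correlation. These lower counts depend on scaling and on the arrays used. With arrays centred on their medians 10 of the beta cell identity list and 12 of the granule list fell. The median log2 change of all genes was then -0.103. With quantile normalization again 5 and 3 fell, and without Adβgal replicates 4, 5 and 6, 3 and 2 did.

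Of the DNA replication and S phase list, 9 of 44 rose, among them Mcm5 1.46-fold (0.55, adjusted p = 0.014, and 0.36, adjusted p = 0.13, without Adβgal replicates 4, 5 and 6), and 1 fell; 15 rose and 2 fell adjusted over the list alone. It had adjusted p = 3.6e-06, and adjusted p = 0.29 with an estimated correlation, and without Adβgal replicates 4, 5 and 6, 1 member rose and 1 fell. Of the G2 and mitosis list, 1 of 50 rose, Birc5, at 1.49-fold with adjusted p = 0.028; 0 passed adjusted over the list alone. The call of Birc5 was lost without untreated replicate 2 (0.07), 3 (0.059), 4 (0.054) or 5 (0.074) and without Adβgal replicates 4, 5 and 6 together (0.072), where its log2 change was 0.63, against 0.57. The list had adjusted p = 2.9e-05, and adjusted p = 0.37 with an estimated correlation.

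Camera also passed towards higher values the lists of acinar markers (3.8e-06, median 0.96, and adjusted p = 0.5 with an estimated correlation), endothelial markers (0.00086, and adjusted p = 0.53 with an estimated correlation), disallowed genes (0.0031, and adjusted p = 0.37 with an estimated correlation) and NF-κB (0.0055, and adjusted p = 0.39 with an estimated correlation). Against that direction, the members past the threshold in the acinar and disallowed lists were lower: Bhlha15, an acinar transcription factor gene, by 1.71-fold and Arap2 by 1.3-fold. Those of the endothelial and NF-κB lists were Flt4, at 1.25-fold higher, and the cytokine gene Il6, at 1.89-fold higher, each with adjusted p = 0.048. Adjusted over the list alone, 1 acinar member was higher and 1 lower, 1 disallowed gene was lower, and 0 endothelial and 0 NF-κB members passed limma; adjusted over all genes with arrays centred on their medians, 1 acinar member was higher and 1 lower. The call of Flt4 was lost without any 1 untreated array or Adβgal replicate 2, 3, 4, 5 or 6 (0.052 to 0.12), and that of Il6 without any 1 untreated array or Adβgal replicate 1, 3, 4, 5 or 6 (0.058 to 0.13). Without Adβgal replicates 4, 5 and 6 together the log2 change of Flt4 was 0.35, against 0.32 (adjusted p = 0.11), and that of Il6 was 0.63, against 0.92 (adjusted p = 0.21). Without Adβgal replicates 4, 5 and 6 these 4 lists had adjusted p-values of 0.39, 0.26, 0.14 and 0.53 in the order given. The other 11 lists did not pass, though members did, such as the thioredoxin inhibitor gene Txnip, which rose 1.8-fold, and the death receptor gene Fas, which rose 1.62-fold but was not called with the mean of all its probe sets (0.42, against 0.69; adjusted p = 0.066).

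In all, 997 genes changed between Adβgal and untreated islets, 404 higher and 593 lower, and 366 changed at least 1.5-fold (191 higher, 175 lower). With arrays centred on their medians, 17.5% of the genes called were higher, against 40.5%. Quantile normalization again gave 402 higher and 692 lower. Camera passed 10 lists; 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry passed 6. The count of genes was 620, 532, 526 and 509 without untreated replicate 1, 2, 4 and 5, 1503 and 647 without Adβgal replicate 2 and 6, and 552 without Adβgal replicates 4, 5 and 6.

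AdNkx6.1 against untreated joins the virus with the delivered factor. In the listed interferon response, replication and mitosis genes 43 of 45, 38 of 44 and 37 of 50 were higher, and in those of beta cell identity and other endocrine cells 14 of 20 and 11 of 17 were lower. These lists passed camera at its preset correlation but not with an estimated one (0.1 to 0.11). The highest fitted rises were in Ly6i at 45.4-fold, Slc5a5 at 39.2-fold, Bpifb1 at 32.5-fold, Catsperz at 26.3-fold and Slfn4 at 19.9-fold. Untreated Ly6i (3.48), Slc5a5 (4.26) and Slfn4 (4.92) lay low on the intensity scale, as did Ugt2b15 with AdNkx6.1 (3.45), so these folds and their order are not exact. The highest fitted falls were in Clca2 at 5.25-fold, Ugt2b15 at 4.9-fold, Lrrn3, a leucine-rich repeat protein gene, at 4.22-fold, the calcium-binding protein gene Calb1 at 4.01-fold and Ptf1a at 3.93-fold. Nr4a1 rose 2.96-fold (log2 change 1.57 ± 0.18, adjusted p = 9.1e-06, n = 5 and 5) and Nr4a3 rose 4.92-fold (2.3 ± 0.43, adjusted p = 0.00075). With the mean of all probe sets of a gene the log2 change of Nr4a3 was 1.37 and that of Slfn4 was 2.14, against 4.31. Nkx6-1 fell 1.74-fold (-0.8 ± 0.1, adjusted p = 2.5e-05).

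Of the interferon response list, 43 of 45 rose and 0 fell, 44 adjusted over the list alone, with Oasl 14.7-fold and Irf7 11-fold higher; the list had adjusted p = 9.8e-28, and adjusted p = 0.11 with an estimated correlation. DNA replication members rose in 38 of 44 cases, also 38 adjusted over the list alone, with Cdt1 7.93-fold and Tk1 4.93-fold higher (adjusted p = 6.9e-20, and adjusted p = 0.1 with an estimated correlation). Mitosis members rose in 37 of 50 cases, 42 adjusted over the list alone, with Aurka 3.27-fold higher (adjusted p = 2.2e-15, and adjusted p = 0.11 with an estimated correlation). Of the beta cell identity list, 14 of 20 fell and 0 rose, 15 lower adjusted over the list alone, with Neurod1 1.71-fold and Nkx2-2 1.7-fold lower (adjusted p = 1.4e-06, and adjusted p = 0.11 with an estimated correlation). Of the other endocrine list, 11 of 17 fell, also 11 adjusted over the list alone, with Rbp4 2.57-fold and Hhex 2.05-fold lower (adjusted p = 2.4e-06, and adjusted p = 0.11 with an estimated correlation). Camera also passed the immediate early genes (14 higher, 4 lower; adjusted p = 0.0016, and adjusted p = 0.37 with an estimated correlation), where Fosb rose 7.1-fold, and the p53 targets (8 higher, 3 lower; adjusted p = 0.0052, and adjusted p = 0.18 with an estimated correlation). It passed the granule list towards lower values (2 higher, 12 lower; adjusted p = 0.0068, and adjusted p = 0.47 with an estimated correlation) and the duct markers towards higher values (7 higher, 2 lower; adjusted p = 0.017, and adjusted p = 0.37 with an estimated correlation), where Muc1 rose 2.73-fold. The glycolysis list (8 higher, 1 lower) had adjusted p = 0.026, and adjusted p = 0.37 with an estimated correlation, but 0.053 without AdNkx6.1 replicate 2 and 0.065 without the dimmest 40% of probe sets. Adjusted over the list alone, the counts higher and lower were 18 and 4 for the immediate early genes, 9 and 3 for p53 targets, 2 and 13 for the granule list, 8 and 2 for duct markers and 8 and 1 for glycolysis. The remaining 11 lists did not pass, and in cholesterol synthesis 5 members rose and 6 fell (median -0.12, mean 0).

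In all, 4360 genes changed between AdNkx6.1 and untreated islets, 2404 higher and 1956 lower, and 1807 changed at least 1.5-fold (1222 higher, 585 lower). With arrays centred on their medians, 38.8% of the genes called were higher, against 55.1%. Quantile normalization again gave 2337 higher and 2015 lower. Median array intensities were 264.8 to 280.1 untreated and 281.5 to 296.2 with AdNkx6.1, so centring also removes a difference between these groups. Camera passed 10 of 21 lists; 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry passed 11.

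Of the genes called for Adβgal, 248 were also called higher and 386 also called lower with AdNkx6.1 against the same untreated arrays, which is 634 genes or 63.6%. Independent lists would share 68.3 and 81.6, a figure that leaves out the shared untreated arrays. The 100 simulated draws of unchanged groups shared at most 1. Unchanged groups give few calls at all, so this low count was set in advance. It does not measure the overlap that comes from shared arrays. Fold changes of all genes had the same sign in 66.8%, against 67.5% in the draws, and a correlation across genes, which are not independent replicates, of 0.46 against 0.52. Their covariance was 0.071, against 0.015 in the draws. With the untreated arrays split between the comparisons in 10 ways, the covariance was 0.061 to 0.069 and the correlation 0.36 to 0.44. Shared calls then numbered 39 to 110, but each comparison had fewer untreated arrays and so less power to call genes. The overlap by chance of those calls was not computed. The shared calls were 420, 339, 336 and 336 without untreated replicate 1, 2, 4 and 5. Another 40 genes were called in opposite directions, among them Scd, with a log2 change of -1.48 with Adβgal and 1.34 with AdNkx6.1, and the sterol reductase gene Dhcr7, at -0.5 and 0.31.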

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

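For Prm1, the explanations by other spermatid genes and by a virus sequence were both tests chosen only after the result was seen. The Prm1 probe set had a mean intensity of 5090 with Adβgal, 86.4 with AdNkx6.1 and 14.6 untreated. Expression of other spermatid genes was excluded: the median log2 change of 35 such genes was -0.11 between Adβgal and untreated, with 0 called higher and 1 lower. A sequence carried by the virus, such as a protamine polyadenylation signal in a reporter cassette, could give such a signal. All 11 virus arrays lay above the highest untreated array, which cannot tell it from another effect of virus. The Adβgal arrays lay at log2 11.69 to 12.73 and the AdNkx6.1 arrays at 6 to 6.71. This argues against an effect of equal size with both viruses. The sequence of the delivered virus was not used here.

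For Adβgal replicates 4, 5 and 6, which stand apart from replicates 1 to 3, every one of the tests, including those that leave these replicates out or use the actin ratio, was chosen only after the result was seen. Carried-over acinar tissue could account for part of it, with an acinar list mean of 1.1 or more on each against at most 0.49 on replicates 1 to 3, but the arrays were picked by their values and no test compared them. Lymphoid tissue stays open. The B cell genes Cr2, Ms4a1 and Iglc1 were chosen after their values were seen. Their mean log2 intensity was 4.04, 7.36 and 7.13 on replicates 4, 5 and 6. It was at most 3.32 on replicates 1 to 3, and 6.74 on AdNkx6.1 replicate 1. The T cell gene Cd3d, chosen likewise, was 6.14, 6.52 and 5.07 on replicates 4, 5 and 6. Its value was at most 3.84 on replicates 1 to 3 and at most 4.04 on all arrays of the other groups. Another T cell gene, Lck, was higher with AdNkx6.1 than with Adβgal, also without replicates 4, 5 and 6 (log2 change 1.19). Cd3d alone therefore does not settle it. RNA degradation fits replicate 5, with an actin 3'/5' ratio of 40.9, and stays open for replicates 4 and 6, whose 10.4 and 10.5 lay above the 5.91, 9.42 and 6.73 of replicates 1 to 3 but below the highest 15.5 of the other groups. For AdNkx6.1 against Adβgal the acinar list median was -0.08 without these 3 arrays, a test that leaves out arrays with high acinar values. Against untreated islets, which uses no Adβgal array, it was also -0.08, with 0 of 26 members higher and 2 lower. Camera there gave adjusted p = 0.57, and 0.93 with an estimated correlation. These values argue against a fall of the list as a whole apart from these 3 arrays. Ptf1a was still called without them (-1.48, limma adjusted p = 0.011) and had a log2 change of -1.97 against untreated. Its fall therefore does not rest on these arrays alone.

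For the probe sets without a gene name, the tests on Adβgal replicates 4 to 6, on RNA degradation and on low intensity were all chosen only after the result was seen. Between Adβgal and untreated, 978 of 10216 such probe sets were called higher and 546 lower, that is 64.2% higher, against 40.5% of named genes. The share was 66.5% without Adβgal replicates 4, 5 and 6 and 59.7% with the actin 3'/5' ratio as a covariate. Neither explains it as a whole. It was not recomputed with other array scalings, so a part for scaling is untested. Centring arrays on their medians moved the named genes from 404 higher and 593 lower to 313 and 1473, and quantile normalization again to 402 and 692. Of the 10216 probe sets, 436 had several gene symbols rather than none. Over 4 intensity bins cut at the quartiles of the unnamed probe sets, from dim to bright, the share higher was 52, 40.2 and 20.1 points above that of named probe sets. In the brightest bin it differed by -15.3 points. Of the named probe sets called in the other bins, 25% of 32, 43.2% of 139 and 48.6% of 315 were higher. For those bins this argues against low intensity alone. The brightest bin had no such excess, so a part for intensity stays open. No biological explanation was tested.

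Whether chance can be excluded was tested by regrouping the arrays, planned before the result was seen. In each comparison 100 splits were taken, the real one among them, and no other split reached the real count. A chance labelling of these arrays can be excluded at that resolution. Relabelling cannot tell the treatment from a difference in preparation between the groups. The real counts and the highest other were 3560 and 2589 for AdNkx6.1 against Adβgal, 997 and 20 for Adβgal against untreated, and 4360 and 0 for AdNkx6.1 against untreated.

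Single arrays lay far from the rest of their group in 15 of 309 groups of values, and chance alone sets apart about 1 in 20 groups. Values are log2 intensities, with the nearest other array of the group in brackets. On Adβgal arrays these were Ly6i at 5.68 (4.1) and Ube2s at 11.18 (11.55) on replicate 5, Mmp13 at 4.97 (6.45) on replicate 6, and Eno1 at 13.2 (13.44) and Arap2 at 10.57 (10.89) on replicate 4. On untreated arrays they were Slfn4 at 5.76 (4.85) on replicate 5 and, on replicate 3, Scd at 8.53 (9.18), Nkx2-2 at 12.07 (12.21) and Mcm6 at 10.11 (9.79). On AdNkx6.1 arrays they were Tk1 at 10.05 (10.37) on replicate 2, Pyy at 13.79 (13.42) on replicate 3, Xpc at 10.15 (9.94) on replicate 5 and Lck at 8.5 (7.86) on replicate 1. The actin 3'/5' ratio of 40.93 (10.49) and the Gapdh ratio of 6.98 (2.34) were on Adβgal replicate 5. No cause was tested for the single genes.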

How the results depend on the processing

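Of 3699 values of gene fold changes under other settings, for 171 results, 3509 kept their call, 173 were weaker, 7 stronger and 10 reversed; the 7 stronger values were all of Nkx6-1 in Adβgal against untreated. Of 566 values for 32 list results, 497 kept their call and 69 were weaker. The cause of the differences was not tested.

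For Adβgal against untreated, 997 genes changed. With the replicate number as a fixed block the count was 393, and 219 at 1.5-fold or more; the deposited labels do not establish that equal numbers were paired. It was 521 with only the 2 groups compared, 1790 with array weights and 1786 with arrays centred on their medians. It was 2101 with the actin 3'/5' ratio as a covariate, and 552, or 195 at 1.5-fold or more, with Adβgal replicates 4, 5 and 6 left out. Without 1 array it ran from 509 (untreated replicate 5) to 1503 (Adβgal replicate 2), and at 1.5-fold or more from 248 to 566 without the same arrays. With every probe set on its own it was 2685, or 1472 at 1.5-fold or more. In that setting AdNkx6.1 against Adβgal gave 6196 and 3161, and AdNkx6.1 against untreated gave 3060 at 1.5-fold or more. Array weights gave 7469 for AdNkx6.1 against untreated.

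Camera with an estimated correlation passed 0 lists for AdNkx6.1 against Adβgal, 0 for Adβgal against untreated and 0 for AdNkx6.1 against untreated. For Adβgal against untreated, fry passed 6 and with the block 4, and camera passed 6 without Adβgal replicates 4, 5 and 6. The mixed fry test passed 18 there and 18 for AdNkx6.1 against untreated.

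The small Nr4a1 change of -0.01 between Adβgal and untreated was 0.06 with array weights and 0 with the covariate, and ran from -0.12 without Adβgal replicate 5 to 0.13 without replicate 1. The Nr4a3 change of -0.17 was 0.07 with the mean of its probe sets, and ran from -0.45 without Adβgal replicate 5 to 0.15 without replicate 4. The genes shared by the virus comparisons, 634, ran from 336 without untreated replicate 4 to 828 without Adβgal replicate 2. They were 389 without Adβgal replicates 4, 5 and 6, and 39 at the lowest with the untreated arrays split.

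Calls of named genes also ended in other settings. With the replicate number as a fixed block, those of Actg2, Cpa1, Kcnj11, Cuzd1, Dcn, Flt4 and Tagln ended for AdNkx6.1 against Adβgal, and those of Cxcl13, Fstl5, Trem2, Birc5, Rab3b, Arap2, Flt4, Il6 and Mcm5 for Adβgal against untreated. With only the 2 groups compared, those of Actg2, Kcnj11, Cuzd1, Flt4 and Tagln and those of Cxcl13, Fstl5, Trem2, Rab3b, Flt4, Il6 and Mcm5 ended in the same order. With array weights, Actg2 (-1.15, adjusted p = 0.11), Dcn (-0.25, 0.062), Tagln (-0.19, 0.16), Cxcl13 (2.44, 0.066) and Il6 (0.79, 0.051) were not called. Lnc215 was still called there, at -1.41. With a random block Actg2, Flt4, Tagln and Il6 were not called, with quantile normalization again Actg2, Flt4 and Il6, with a variance trend and with the covariate Flt4, and with centring Flt4 in Adβgal against untreated.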

Other observations

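The genes of this section were chosen after their values were seen. The hormone genes Ins1, Ins2 and Gcg lay near the top of the intensity scale, with Ins1 at 14.75, 14.72 and 14.69, so a change in them is hard to see on these arrays. They passed in no comparison. Ppy was lower with AdNkx6.1 than with Adβgal (-0.21, limma adjusted p = 0.042), while Sst (0.083) and Iapp (0.76) did not pass. Against untreated islets Sst (-0.26, 0.0053), Ppy (-0.24, 0.02) and Iapp (-0.18, 0.048) were lower with AdNkx6.1. Among cyclins that start the cell cycle, Ccnd3 was 1.66-fold higher with AdNkx6.1 than with Adβgal (log2 change 0.73 ± 0.07, adjusted p = 1.1e-06). Ccnd1 (0.2, adjusted p = 0.24) and Ccnd2 (0.3, adjusted p = 0.3) did not pass, and neither did Nr4a2, the third receptor of the NR4A family (0.42, adjusted p = 0.083).

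Of the 40 genes called in opposite directions by the virus comparisons, the desaturase gene Scd had, against untreated islets, a log2 change of -1.48 with Adβgal and 1.34 with AdNkx6.1, Fads1 of -0.65 and 0.43, Mvd of -0.44 and 0.34, and the lysolipid transporter gene Mfsd2a of -0.66 and 1.18. The cholesterol synthesis list as a whole did not show this, with 5 members higher and 6 lower for AdNkx6.1 against untreated. Beyond the 10 largest rises against Adβgal lay Prss30 at 10.8-fold, the sulfotransferase gene Sult2b1 at 8.71-fold and the synaptic pentraxin gene Nptx1 at 8.04-fold. Calb1, a calcium-binding protein gene, was 3.5-fold lower, and Fgfr2, a growth factor receptor gene, 3.19-fold lower.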
